A study of Sus scrofa with 3 samples.

How the data were processed

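RNA of 3 cultures of the porcine intestinal epithelial line PIE (ETEC, TL2937+ETEC and TL2766+ETEC, 1 culture each) was measured on 1-colour Agilent porcine arrays. Per the labels' protocols, 200 ng of RNA per sample was labelled with Cy3. Groups were taken from the labels alone. All 3 arrays lay on 1 slide, each at a position of its own, so array position, culture and group cannot be told apart, and a slide block could not be fitted.

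Per the file headers, the processed intensity of each spot was made with Agilent Feature Extraction 10.7.3.1, which subtracted a fitted spatial background, corrected a multiplicative trend within the array and replaced signals near 0 with surrogate values. No normalization between arrays is recorded there. The deposited mean and local background intensities are, per the file headers, those before subtraction. The authors' value table held the same processed intensity, rounded: its values differed by at most 0.496%, 0.492% and 0.496% on the ETEC, TL2937+ETEC and TL2766+ETEC arrays, and its medians were 37, 40.9 and 38.8. Its scale is therefore linear and uncentred.

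The processed intensity was put on the log2 scale and the array's 75th percentile of log2 values was subtracted. Control spots and outlier spots (8, 9 and 4 per array) were left out, and no spot was saturated. Spots of a probe were averaged, and a gene was represented by its probe with the highest mean log2 value. Scaled intensities are these values on a linear scale, multiplied by the geometric mean of the 75th percentiles (481). Of 43603 probes, 13900 had a symbol, for 6523 genes, 29697 had none, and 28 matched several genes, of which 22 kept the array's own name, which was among the matches, and 6 were not named. Names came from the array design, and 3343 probes with no usable name were named through accessions, while 618 were renamed through accessions and 72 through synonyms in a RefSeq table of assembly Sscrofa11.1. The array name was kept where none matched. Some symbols differ from the array name: PTGS2 is PGHS-2 on the array, SLA-DQA1 is SLA-DQA, CTGF is CCN2 and NR4A3 is NOR-1, while CCL11, OSM, FOXH1, IRS1, SFRP5, TFPI, KIF23 and ADAMTS4 carry gene identifiers there. A few list members rest on such a change of name: NIFK in the cell cycle list is MKI67 on the array, and RPL13A in the ribosomal list is FLT3LG.

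With 1 array per group no test of a gene was made. A gene was called where it differed at least 2-fold and was well above background, by the scanner software's flag, on both arrays. A gene well above background on only 1 of the arrays was given a bound, the brighter value over the higher of its own dim value and the lowest detected signal of that array. The named genes followed a rule fixed before the data were examined: up to 12 genes per direction and comparison by size, passing over genes whose other probes disagreed, plus up to 5 bounds per direction and the 4 members of each gene list that differed most. A few genes that the rule names are not reported here. The 35 gene lists were fixed before the data were examined too. For each of 105 list medians, the percentile among 10000 random lists of the same size, matched in 20 bins of mean level, was computed.

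The relation between the lactobacillus differences, which share the ETEC array, was set against 100 simulated draws of unchanged arrays with equal noise. The alternatives tried were a normexp background correction with an offset of 50, quantile, median, cyclic loess and spike-in scaling, the authors' table, other background filters, the mean of all probes of a gene, outlier spots kept and thresholds of 1.5-fold and 3-fold. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.

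The steps were tested on simulated data. Every spot had the same independent noise, dim or bright, and no variation between cultures was simulated. The share of false calls among real cultures was therefore not tested. In the comparison of TL2937+ETEC with ETEC (4976 genes), 50 of 50 genes planted at 3-fold, 25 of 50 at 2-fold, 4 of 50 at 1.5-fold and 0 of 4756 unchanged genes were called. In that of TL2766+ETEC with ETEC (4950 genes) the numbers were 50, 26, 2 and 0 of 4730, and in the direct comparison (4990 genes) 50, 28, 1 and 0 of 4770. Of 200 unchanged lists, 7, 8 and 11 lay outside the central 95%.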

Results

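Gene expression was measured in PIE cells, a non-transformed line of porcine intestinal epithelial cells that was derived from the gut of a newborn pig that had not suckled. The cells were grown for 3 days, kept for 48 h with or without lactobacilli and washed, and then exposed for 12 h to ETEC PAMPs. These are pathogen-associated molecular patterns of enterotoxigenic Escherichia coli, a cause of diarrhoea in young pigs. The lactobacilli were Lactobacillus jensenii TL2937 or Lactobacillus plantarum TL2766. The 3 groups are called ETEC (no lactobacilli), TL2937+ETEC and TL2766+ETEC, and each had 1 array. Unchallenged cells, a further group of the design, were not analysed here, so no value is set against the resting state. With 1 culture per group there was no spread between replicates, and no p-value or standard error is given for any difference below. The number of arrays limits the precision of every value.

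On the 3 arrays the 75th percentile of the processed intensity was 459 (ETEC), 503 (TL2937+ETEC) and 481 (TL2766+ETEC), and 60.9%, 62.5% and 61.7% of the gene spots were well above background. Of 6523 genes with a symbol, 5068, 5123 and 5104 were well above background on these arrays. Over 25 probes with 5 spots each, the median standard deviation of log2 intensity was 0.096 on the ETEC array, 0.10 on the TL2937+ETEC array and 0.12 on the TL2766+ETEC array. Some probes varied more. The highest standard deviation of a log2 difference over 5 spots was 0.39 for TL2937+ETEC against ETEC. It was 0.70 for TL2766+ETEC against ETEC and 0.52 between the lactobacillus arrays. These spreads cover spots, not cultures. A gene is called higher or lower where it differed at least 2-fold and was well above background on both arrays. For other genes the log2 difference is given. A gene list is described by its median log2 difference, over the members detected on any of the 3 arrays, and by the percentile of that median among 10000 random lists of the same size and signal, which describes these arrays and tests no treatment. Of 35 lists, 15 lay outside the central 95% of random lists in the TL2937 comparison with ETEC, 13 in the TL2766 comparison with ETEC and 13 in the direct comparison. Lists of unrelated genes would give about 5%. Members of these lists can vary together between cultures, some lists share members, and the 3 comparisons share arrays. The 5% is therefore no measure of chance for them.

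The comparison of TL2937+ETEC with ETEC asked how cells pretreated with L. jensenii TL2937 differed from cells without lactobacilli after ETEC PAMPs. Every array was of cells exposed to the PAMPs, and none held cells with lactobacilli alone. An altered response to the PAMPs therefore cannot be told apart from an effect of the lactobacilli by themselves. Genes of the interferon response, of antigen presentation, of the chemokine family and of complement had lower signals in the cells pretreated with TL2937. The 36 interferon-stimulated genes had a median log2 difference of -0.52, a median 1.43-fold lower, which lay below all 10000 random lists. All 36 had a difference below 0, 31 of them were at least 1.2-fold lower and 5 were within 1.2-fold. The members that differed most were OASL (-0.94) and OAS1 (-0.90), of the antiviral oligoadenylate synthetase family, PARP14 (-0.76) and the membrane protein IFITM1 (-0.71). No member reached 2-fold.

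MHC class II genes, which present peptides to helper T cells, had a median log2 difference of -0.51 on the TL2937+ETEC array. Of the 10 members, 6 were at least 1.2-fold lower and 4 were within 1.2-fold. SLA-DQA1 differed by -0.83, SLA-DMA by -0.61 and SLA-DRA by -0.57. The 18 genes of MHC class I and antigen processing had a median of -0.36, with 11 at least 1.2-fold lower and 7 within 1.2-fold. The immunoproteasome subunits PSMB8 and PSMB9 differed by -0.58 and -0.50, SLA-3 by -0.46 and the peptide transporter subunit TAP1 by -0.44. Both medians lay below all 10000 random lists. SLA genes of the same class resemble each other closely, and their probes may bind transcripts of each other.

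The 22 chemokines had a median log2 difference of -0.28, below all 10000 random lists, with 10 of the 21 measured on both arrays at least 1.2-fold lower, 11 within 1.2-fold and 0 at least 1.2-fold higher. CCL11, the eosinophil attractant eotaxin, was 1.996-fold lower, while the log2 difference was -0.92 for CCL21, -0.80 for CCL8 and -0.64 for the interferon-induced CXCL9. CXCL9, CXCL10 and CXCL11 stand in both the chemokine and the interferon lists. Of 19 complement genes, 10 were at least 1.2-fold lower and 9 were within 1.2-fold. Their median was -0.28, at percentile 0.02. SERPING1, which encodes the C1 inhibitor, differed by -0.83, complement factor B (CFB) by -0.78, the protease C1S by -0.74 and C3 by -0.58. With a normexp background correction, the medians were -0.18 for chemokines and -0.15 for complement. Among the 14 chemokines above the median signal of the detected probes on both arrays, the median was -0.18.

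The cytokine list and the list of NF-kB targets did not stand apart in this comparison. Their medians were -0.075 (percentile 26.3) and -0.082 (percentile 20.6). In the cytokine list OSM differed by -0.72 and TNFSF13B by -0.45, and in the NF-kB list, after the complement genes CFB and C3 given above, SELE differed by 0.42. IL6, CXCL8 and TNF, chosen after their values were seen, differed by -0.19, -0.17 and 0.033. The median of the pattern recognition list, which holds the Toll-like receptors and their adaptors, was -0.047 (percentile 36.2), although its members TLR2 and TLR3 differed by -0.67 and -0.54. The 8 negative regulators of Toll-like receptor signalling had a median of -0.099 (percentile 19.4), with PTPN6 at -0.39 and NLRC3 at -0.28.

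Further lists with medians outside the central 95% of random lists in this comparison were mostly lower on the TL2937+ETEC array. Immediate-early genes had a median of -0.21 (percentile 0.11), with EGR1 at -0.63 and CTGF at -0.52. Genes of the integrated stress response had a median of -0.20 (percentile 0.08), with STC2 at -0.41. Growth factors of the epithelium had a median of -0.19 (percentile 0.36), although the member that differed most, IGFBP6, lay at 1.54. IGF1 lay at -0.82 and BMP4 at -0.70. Genes of glycolysis and hypoxia had a median of -0.15 (percentile 0.46), with ADM at -0.82 and hexokinase HK2 at -0.70. Extracellular matrix genes had a median of -0.15 (percentile 1.36), with MMP7 at -0.75. Cholesterol synthesis had a median of 0.16 (percentile 99.99), with HSD17B7 at 0.51 and squalene epoxidase (SQLE) at 0.31. Targets of NRF2, the regulator of antioxidant genes, had a median of 0.031 (percentile 99.0), with HMOX1 at 0.48 and NQO1 at 0.34. Of the 19 NRF2 targets measured on both arrays, 17 were within 1.2-fold and 2 at least 1.2-fold higher. Within 1.2-fold were also 11 of 14 cholesterol genes and 16 of 22 genes of glycolysis and hypoxia. Cell cycle genes had a median of 0.073 (percentile 97.55), with the replication gene MCM3 at 0.59, coagulation genes of 0.065 (percentile 98.2), with F2 at 1.12, THBD at -0.67 and TFPI at 0.67, and apoptosis and p53 genes of -0.13 (percentile 1.42), with CCNG1 at -0.38. The percentiles of these 3 lists reached 97.15, 96.7 and 7.1 under other scalings, inside the central 95%. With the normexp correction the cell cycle median was 0.035 and the coagulation median 0.034, and the latter was 0.023 with the mean of all probes and 0.016 without a background filter. The NRF2 median ranged from 0.014 to 0.086 over the alternatives, and the extracellular matrix median was -0.091 with cyclic loess. Ribosomal protein genes had a median of -0.13 (percentile 4.49, and 1.85 with the normexp correction) and reference genes of -0.12 (percentile 17.3), against -0.040 for all genes.

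Of 4975 genes well above background on both arrays, 12 were at least 2-fold higher and 7 at least 2-fold lower on the TL2937+ETEC array. Somatostatin (SST), a peptide hormone, was 4.53-fold higher, at scaled intensities of 107.5 against 23.8. P-selectin (SELP), an adhesion molecule, was 3.20-fold higher, at 15790 against 4943. SMOC1 was 3.07-fold, the thyrotropin-releasing hormone receptor TRHR 2.75-fold and the transcription factor FOXH1 2.66-fold higher. On the ETEC array TRHR lay at 17.5, near its lowest detected signal (12.9). The Wnt receptor ligand NDP was 2.48-fold, the activin-binding protein follistatin (FST) 2.47-fold, the collagen COL21A1 2.21-fold, prothrombin (F2) 2.17-fold and the ammonium transporter RHCG 2.14-fold higher. The peptidase-like gene NAALADL1 was 3.01-fold lower, at 14.2 against 42.7, near the lowest detected signal of the TL2937+ETEC array (11.6). The glutamate transporter SLC1A1 was 2.38-fold lower, and tropomyosin TPM1 was 2.33-fold lower, from 38050 to 16350. The insulin receptor substrate IRS1 was 2.22-fold, the Wnt antagonist SFRP5 2.17-fold and the water channel AQP3 2.03-fold lower. All 21 measured probes of TPM1 and all 4 of SLC1A1 differed in the same direction, the others of TPM1 by 0.62 to 1.23 log2 units. The other measured probe of SST gave a log2 difference of 1.28. IGFBP6 (log2 difference 1.54) and STRA6 (-1.42) had a probe that went the other way, at -0.045 and 0.60. With both arrays required to be above the median signal of the detected probes, 4 genes were higher and 2 lower.

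Some genes were well above background on only 1 of these arrays and have only a bound. CRABP2, which binds retinoic acid, was at least 5.07-fold higher on the TL2937+ETEC array, and the nuclear receptor NR0B2 at least 3.52-fold higher. OTOR was at least 6.53-fold and MYL1 at least 5.58-fold lower. The brighter signal of each was dim, at 65.3, 45.3, 75.4 and 64.5.

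**Figure D1:**
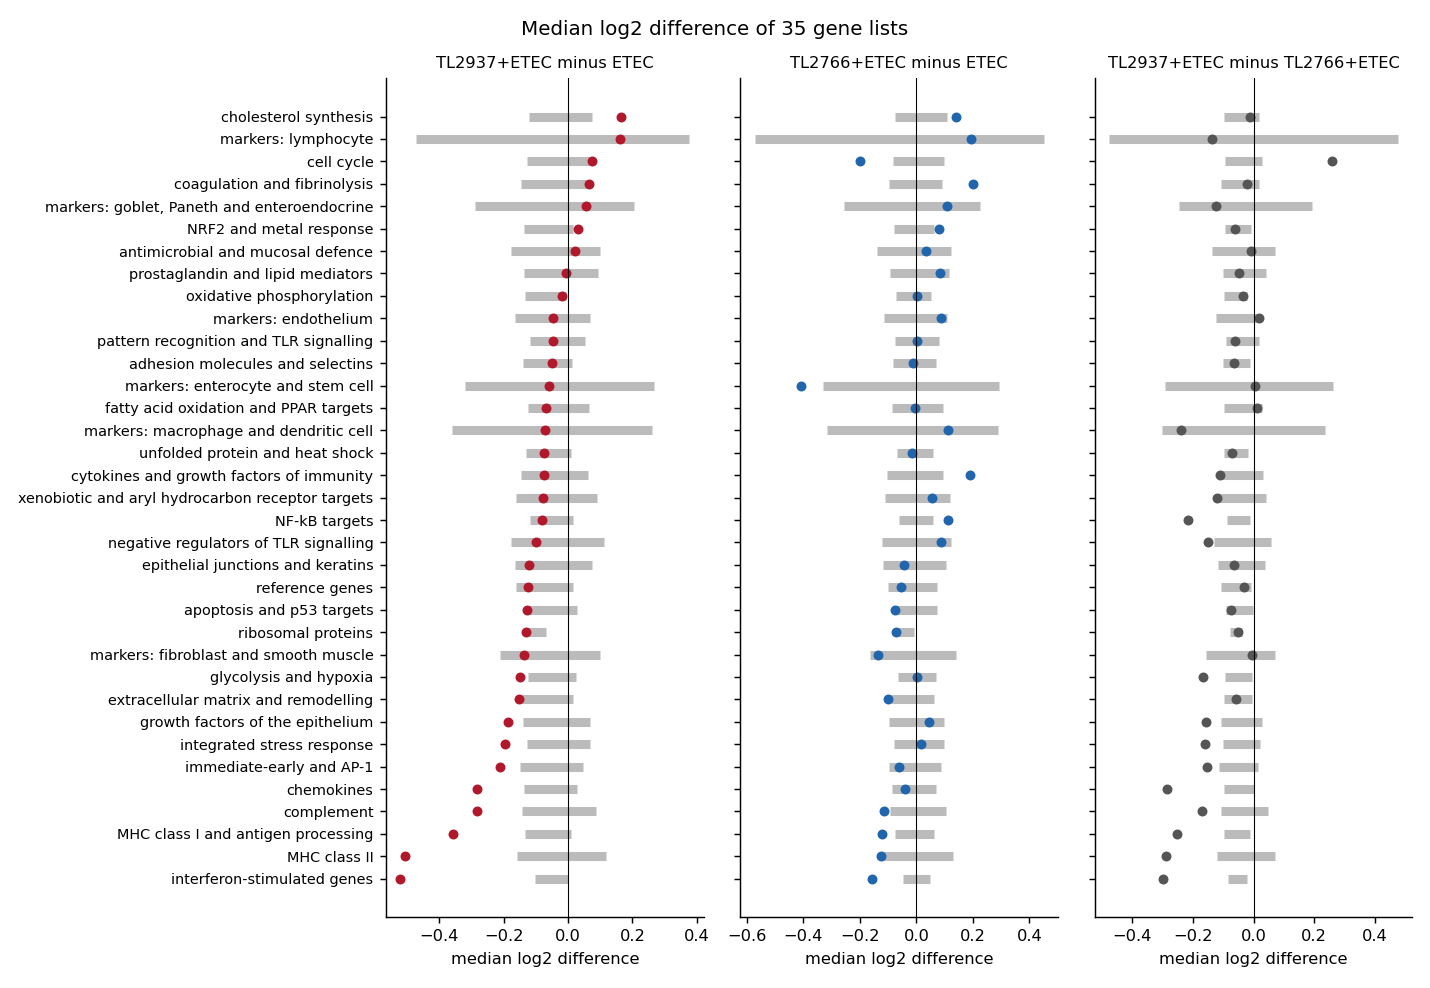
Median log2 difference of each of 35 gene lists (points) in the 3 comparisons, with the central 95% of the medians of 10000 random lists of the same size and signal (grey bars); the x axis is the log2 difference. On the TL2937+ETEC array the interferon-stimulated genes lay at -0.52 against ETEC, and on the TL2766+ETEC array they lay at -0.16.

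The comparison of TL2766+ETEC with ETEC asked the same question of L. plantarum TL2766. Here the medians of the NF-kB and cytokine lists lay above those of random lists, and those of the cell cycle, interferon and complement lists below them. The 27 NF-kB targets had a median log2 difference of 0.11 (percentile 99.99), with 9 at least 1.2-fold higher, 1 at least 1.2-fold lower and 17 within 1.2-fold. E-selectin (SELE) differed by 0.66, the cytokine CSF2 by 0.64, the prostaglandin synthase PTGS2 by 0.59 and IL6 by 0.52. The 24 cytokines had a median of 0.19 (percentile 99.96). Of the 21 measured on both arrays, 7 were at least 1.2-fold higher, 4 at least 1.2-fold lower and 10 within 1.2-fold. TGFB3 differed by 0.73, IL27 by 0.57 and IL7 by -0.61. CSF2, IL1A, IL6 and TNF stand in both lists. The median of the cytokine list was 0.046 (percentile 98.15) with the normexp correction, 0.12 with the mean of all probes and -0.0046 without any background filter.

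The chemokine list did not stand apart on the TL2766+ETEC array. Its median was -0.039 (percentile 23.3), with 3 members at least 1.2-fold higher, 2 at least 1.2-fold lower and 15 within 1.2-fold. CCL3L1 differed by -0.52, CCL20 by 0.46 and CCL4 by 0.41. Interferon-stimulated genes had a median of -0.16, below all 10000 random lists, with 7 of 36 at least 1.2-fold lower and 29 within 1.2-fold. IFI44 differed by -0.36 and OASL by -0.33. Complement genes had a median of -0.11 (percentile 1.195), with C3 at -0.45 and SERPING1 at -0.42. With the normexp correction that median was -0.059 (percentile 11.4). MHC class I genes had a median of -0.12 (percentile 0.11), with PSMB8 at -0.29. MHC class II genes had a median of -0.12 (percentile 2.43), with RFX5, a transcription factor for these genes, at 0.37 and SLA-DQA1 at -0.31. The class II median was -0.070 (percentile 10.72) with the normexp correction and -0.23 above the median signal of the detected probes.

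Cell cycle genes had a median log2 difference of -0.20 on the TL2766+ETEC array, below all 10000 random lists, with 5 of 21 at least 1.2-fold lower, 1 at least 1.2-fold higher and 15 within 1.2-fold. The mitotic kinesin KIF20A differed by -0.67, the centromere protein CENPF by -0.38 and the mitotic activator CDC20 by -0.32. Coagulation genes had a median of 0.20, above all 10000 random lists, with 9 of the 15 measured on both arrays at least 1.2-fold higher, 1 at least 1.2-fold lower and 5 within 1.2-fold. Prothrombin (F2) differed by 1.07, coagulation factor F12 and the inhibitor TFPI each by 0.61, and thrombomodulin (THBD) by -0.52. Cholesterol synthesis had a median of 0.14 (percentile 99.5), with HSD17B7 at 0.54 and SQLE at 0.35. NRF2 targets had a median of 0.080 (percentile 98.9, and 0.052 with spike-in scaling), with NQO1 at 0.53 and HMOX1 at 0.41. Of the 19 measured on both arrays, 16 were within 1.2-fold and 3 at least 1.2-fold higher. Extracellular matrix genes had a median of -0.099 (percentile 1.47, reaching 2.75 under another scaling), with COL1A2 at -0.55 and the protease ADAMTS4 at 0.71. Immediate-early genes lay at -0.061 (percentile 12.1), glycolysis and hypoxia at 0.0020 (percentile 54.7) and the integrated stress response at 0.017 (percentile 58.5), and the sign of the last pair turned under another scaling. Apoptosis and p53 genes had a median of -0.074 (percentile 1.68, reaching 6.3), with CCNG1 at -0.39, but the median was 0.00035 with the mean of all probes. Enterocyte and stem cell markers had a median of -0.41 (percentile 1.06, reaching 6.15) over 8 detected members, but of 0.075 over the 5 measured on both arrays and -0.12 with the normexp correction. The coagulation median was between 0.065 (no background filter) and 0.31 (mean of all probes), and the cholesterol median was 0.089 with the mean of all probes.

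Of 4950 genes well above background on both arrays, 16 were at least 2-fold higher and 12 at least 2-fold lower on the TL2766+ETEC array. SST was 6.30-fold higher, at a scaled intensity of 149.7 against 23.8, while its other measured probe gave a log2 difference of 1.83. The steroid dehydrogenase HSD17B1 was 3.26-fold, SELP 3.19-fold, SMOC1 3.14-fold, FST 3.05-fold and TRHR 2.61-fold higher. NCF1, a gene of the phagocyte NADPH oxidase, was 2.44-fold higher, at a scaled intensity of 39.6. ARHGEF39 was 2.53-fold, the sulfotransferase GAL3ST2 2.35-fold, NDP 2.28-fold and IGFBP6 2.25-fold higher. ADGRE3, named only through a gene identifier on the array and not checked by sequence, was 4.31-fold lower, at 16.5 against 71.0. It was dimmer still on the TL2937+ETEC array, at 11.6. NAALADL1 was 2.81-fold, SFRP5 2.70-fold, LRRC71 2.37-fold, IRS1 2.28-fold and TPM1 2.17-fold lower. MAB21L1 was 2.15-fold, SLC1A1 2.09-fold, the sarcomere protein MYOZ2 2.09-fold and ZNF831 2.04-fold lower, and the Wnt-pathway transcription factor LEF1 had a log2 difference of -1.002. NAALADL1 (15.2) and ZNF831 (13.9) lay near the lowest detected signal of the TL2766+ETEC array (11.8). ZNF831 was dimmer still on the TL2937+ETEC array, at 9.75. The low signals of ADGRE3 and ZNF831 were therefore not particular to TL2766. Other probes gave values as small as 0.038 for IGFBP6 and, in size, 0.32 for MYOZ2, with the same sign. STRA6 (-1.33) and GFAP (1.09) had a probe that went the other way. STRA6 and GFAP fall outside the rule for named genes and were chosen after their values were seen. The normexp correction gave 5 genes higher and 2 lower, so that 71.4% of the calls were higher in place of 57.1%. With both arrays above the median signal of the detected probes, 4 were higher and 2 lower.

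Among genes well above background on only 1 of these arrays, the immediate-early gene EGR4 was at least 5.61-fold higher on the TL2766+ETEC array, PHYHIP at least 4.09-fold and CRABP2 at least 3.99-fold higher. OTOR was at least 6.41-fold and SMCP at least 4.45-fold lower. Their brighter signals were 72.2, 52.7, 51.4, 75.4 and 52.3.

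**Figure D2:**
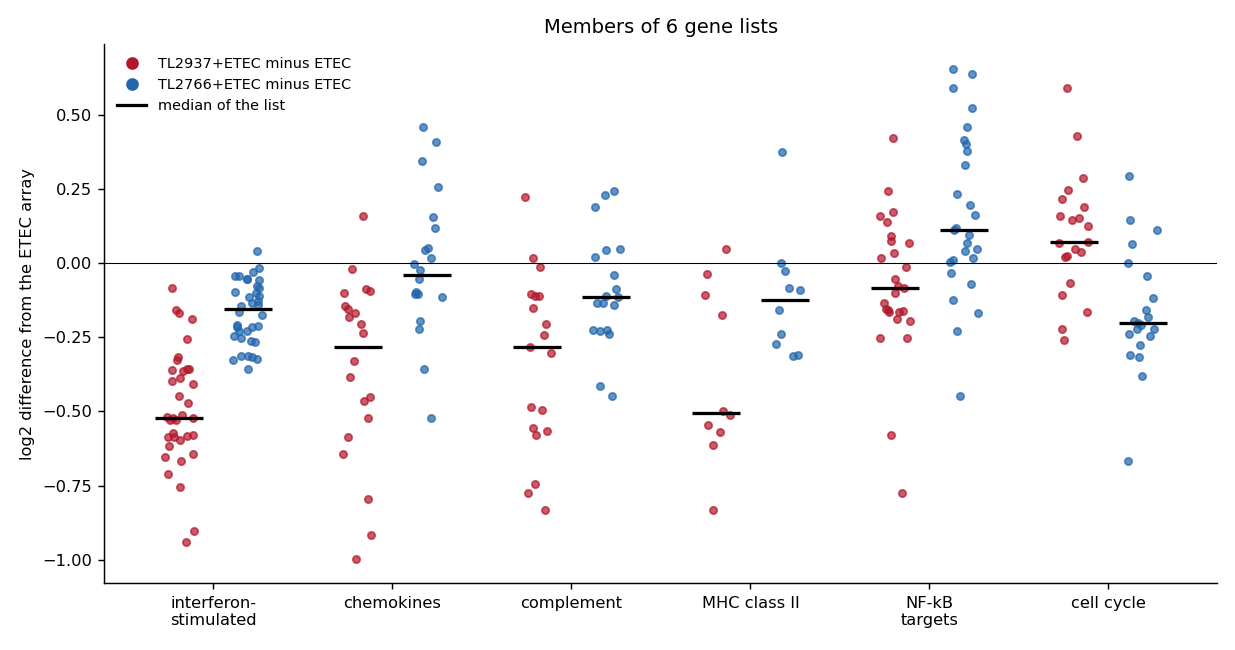
Log2 difference from the ETEC array of each member of 6 gene lists that was well above background on both arrays (points), for TL2937+ETEC and TL2766+ETEC, with each list's median (black lines, over members detected on any array). All 36 interferon-stimulated genes lay below 0 on the TL2937+ETEC array, and the cell cycle medians were 0.073 and -0.20.

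The direct comparison of TL2937+ETEC with TL2766+ETEC asked how the lactobacilli differed from each other. The interferon, chemokine, NF-kB, MHC and complement lists had lower medians, and the cell cycle list a higher one, in the cells pretreated with TL2937. The pattern recognition, adhesion and antimicrobial lists did not stand apart, with medians of -0.062, -0.064 and -0.0078 (percentiles 18.1, 33.5 and 71.5), the last of which turned sign under another scaling. Interferon-stimulated genes had a median log2 difference of -0.30, with all 36 below 0 and 21 at least 1.2-fold lower. OAS1 differed by -0.67, OASL by -0.61 and CXCL9 by -0.55. The chemokine median was -0.29, with 13 of 20 at least 1.2-fold lower and 7 within 1.2-fold. CCL8 differed by -0.85, CCL11 by -0.64 and CXCL11 by -0.53. NF-kB targets had a median of -0.22, with 10 of 27 at least 1.2-fold lower, 17 within 1.2-fold and 25 below 0. PTGS2 differed by -0.75, IL6 by -0.72, CFB by -0.55 and IL1A by -0.50. MHC class II genes had a median of -0.29, with SLA-DQA1 at -0.52 and SLA-DRA at -0.49, and MHC class I genes of -0.25, with PSMB9 at -0.37 and PSMB10 at -0.34. The medians of these 5 lists lay below all 10000 random lists.

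Complement genes had a median of -0.17 (percentile 0.05), with 8 of 19 at least 1.2-fold lower and 11 within 1.2-fold. CFB differed by -0.55, C1R by -0.52 and C1S by -0.51. The complement median was -0.088 (percentile 3.63) with the normexp correction and -0.29 among the 8 members above the median signal of the detected probes. The cytokine list had a median of -0.11 (percentile 1.86), with OSM at -0.96 and TGFB3 at -0.84. The 8 negative regulators of Toll-like receptor signalling all lay below 0 and within 1.2-fold, with a median of -0.15 (percentile 0.97). NFKBIA, an NF-kB inhibitor, differed by -0.26, and IRAK3 by -0.25. Glycolysis and hypoxia genes had a median of -0.17, below all 10000 random lists, with HK2 at -0.56 and lactate dehydrogenase LDHA at -0.46. The integrated stress response lay at -0.16 (percentile 0.06), with GDF15 at -0.67, growth factors of the epithelium at -0.16 (percentile 0.06), with TGFA at -0.71, and immediate-early genes at -0.15 (percentile 0.14), with NR4A3 at -0.46. Cell cycle genes had a median of 0.26, above all 10000 random lists, with 10 of 21 at least 1.2-fold higher and 11 within 1.2-fold. The kinesin KIF23 differed by 0.55, and the mitotic genes PLK1, CDCA3 and CENPF by 0.46, 0.46 and 0.45. Above the median signal of the detected probes, the medians were -0.045 for cytokines, -0.090 for growth factors and -0.072 for immediate-early genes. The cytokine median was -0.17 with the mean of all probes and -0.055 without a background filter. The growth factor median was -0.092 over members above background on either lactobacillus array, and that of glycolysis and hypoxia was -0.11 with the normexp correction.

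Few genes differed 2-fold between the lactobacillus arrays. Of 4991 genes, 4 were higher and 10 lower on the TL2937+ETEC array. FOXH1 was 2.52-fold, LCN5 2.23-fold, LRRC71 2.16-fold and ZNF367 2.12-fold higher. GAL3ST2 was 3.71-fold, ARHGEF39 3.07-fold, the semaphorin SEMA6D 2.56-fold, the glutamate receptor GRM4 2.56-fold, MESP2 2.34-fold and SLA2 2.30-fold lower. EPB42 was 2.27-fold, HKDC1 2.24-fold, ZBTB12 2.13-fold and HSD17B1 2.05-fold lower. With both arrays required to be above the median signal of the detected probes, 0 genes were higher and 0 lower. The normexp correction gave 1 higher and 0 lower, so that 100% of the calls were higher in place of 28.6%. That share rests on 1 call and gives no direction for the comparison. Of genes above background on only 1 of these arrays, NR0B2 was at least 3.85-fold and CD302 at least 3.63-fold higher with TL2937, and EGR4 was at least 6.25-fold and EPO at least 3.86-fold lower.

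**Figure D3:**
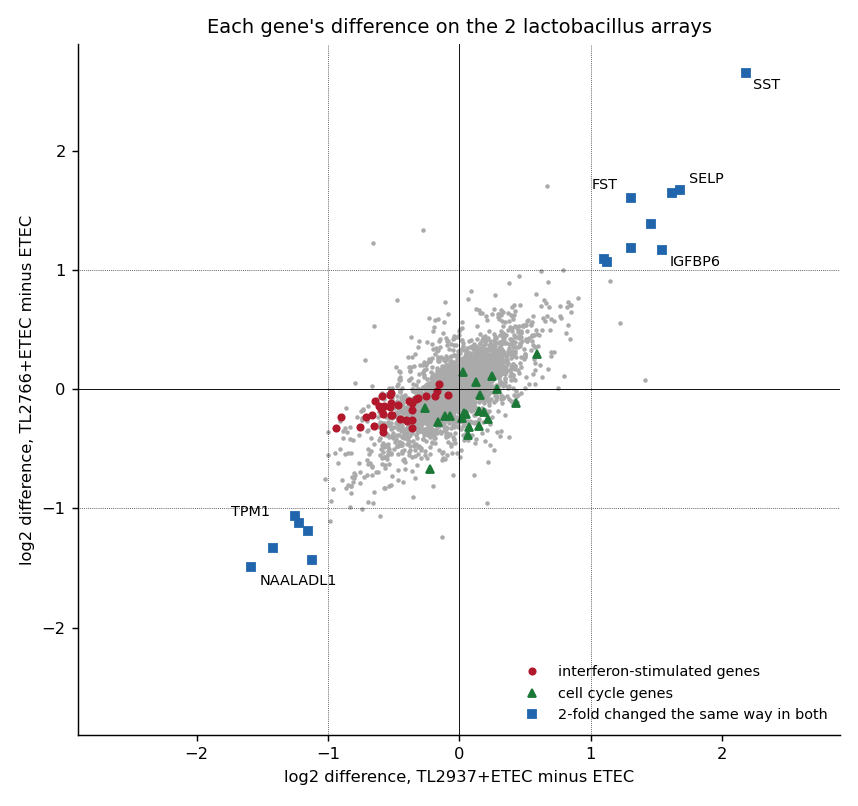
Log2 difference of TL2937+ETEC (x axis) and TL2766+ETEC (y axis) from the same ETEC array for 4922 genes well above background on all 3 arrays, with dotted lines at 2-fold. Across genes r was 0.72, and 15 genes passed 2-fold the same way in both differences.

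Both lactobacillus arrays were compared with the same ETEC array, so their differences share its chance values. Over 4922 genes well above background on all 3 arrays, Pearson's r across genes, which are not independent replicates, was 0.72. In 100 simulations of unchanged arrays with equal noise and a shared control r averaged 0.50, a value fixed by that setting. The covariance was 0.040, against 0.025 simulated with the pooled spread of spots and 0.010 with its median. The pooled spread overstates the noise of most genes: it gives a standard deviation of 0.23 between the lactobacillus arrays, where 0.18 was observed. In sign, 74.7% of genes went the same way, against 66.7% simulated. A larger deviation of the ETEC array or its culture would raise r, the covariance and the share of equal signs without any effect of lactobacilli. The ETEC group had 1 array and could not be split, so these values cannot separate that from an effect common to both lactobacilli.

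The genes called 2-fold in both comparisons were 9 higher and 6 lower, of 12 and 13 higher and 7 and 10 lower among these 4922 genes. Independent lists would share 0.032 and 0.014, but lists that share the ETEC array are not independent. SST, SELP, SMOC1, IGFBP6, TRHR, NDP, FST, F2 and RHCG were higher, and NAALADL1, STRA6, SLC1A1, TPM1, IRS1 and SFRP5 were lower. SELP differed by 1.68 and 1.67 on the TL2937+ETEC and TL2766+ETEC arrays, SMOC1 by 1.62 and 1.65, and TPM1 by -1.22 and -1.12. At most 1 gene was 2-fold changed in any of the 100 simulations, which hold noise between spots but not between cultures. They gave every gene the same noise, taken from 25 probes well above background on all 3 arrays. Of the 15 genes, 9 were not above the median detected signal on all 3 arrays. The simulations therefore do not show how many dim genes would pass 2-fold unchanged. Part or all of the overlap may come from the shared ETEC array and its culture.

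**Figure D4:**
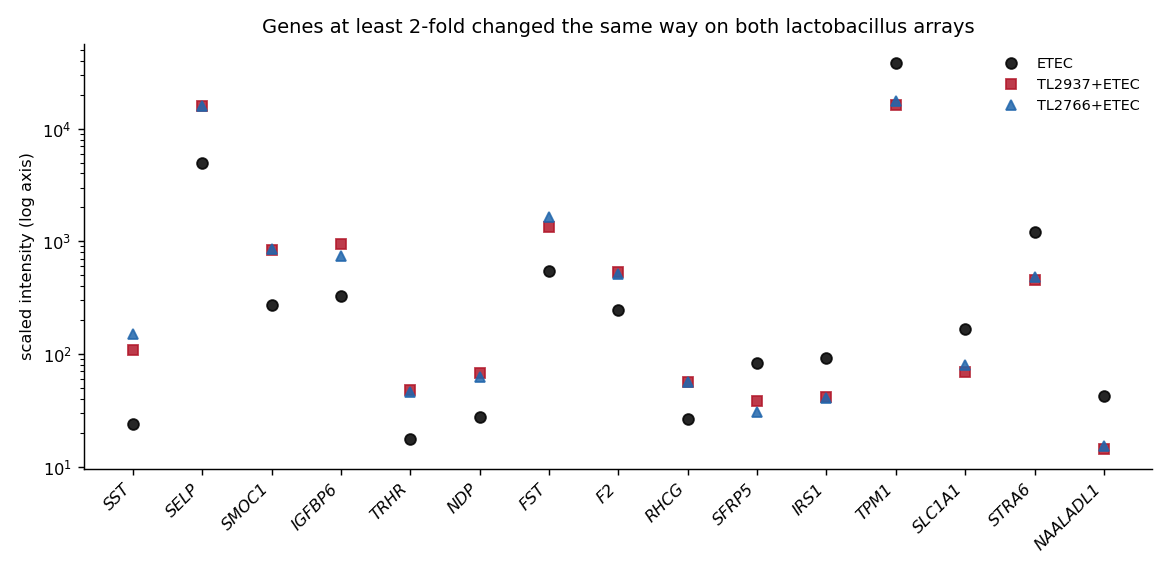
Scaled intensity (log axis) of the 15 genes at least 2-fold changed the same way on both lactobacillus arrays, with 1 point per array. For SELP the ETEC array gave 4943 and the lactobacillus arrays 15790 and 15780.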

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

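The test of genes with only 1 measured probe was chosen after the result was seen, and the other tests before.

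The cell cycle list had medians of opposite sign against the ETEC array, with a log2 difference of 0.07271 on the TL2937+ETEC array and -0.2011 on the TL2766+ETEC array. On the TL2937+ETEC array 18 of 21 members were within 1.2-fold, and the percentile of 97.55 fell to 97.15, inside the central 95%, under another scaling. The difference between the groups was not tested, since each group had 1 array.

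Interferon-stimulated genes were lower on the TL2937+ETEC array than on the ETEC array. Their other probes, 38 probes of 23 genes, had a median log2 difference of -0.4683 (95% bootstrap interval over probes -0.5566 to -0.3998), which argues against an artefact of single probes. The list median was -0.4496 after cyclic loess, which argues against brightness-dependent scaling as the whole cause. It was -0.5082 after the median of the surrounding spots was subtracted. The scanner software had already corrected trends within the array. That subtraction could remove only what was left, so it was a weak test of a local trend. An effect of the TL2937 pretreatment may underlie the pattern, as a hypothesis, but differences between cultures of 1 treatment stay open with 1 culture per group.

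The 15 genes at least 2-fold changed the same way on both lactobacillus arrays kept that change after the surrounding spots' median was subtracted (15 of 15). For 6 of them, 29 other probes had a median signed log2 difference of 0.9968 (bootstrap interval over probes 0.80 to 1.19). Of these probes, 20 were of TPM1, so the interval mostly describes that gene, and it does not cover cultures. In at least 1 comparison 2 probes went the other way. The median over the 6 genes was 0.988. For the 9 others no other probe was measured, so a probe artefact and a true change cannot be told apart. Dim spots may account for part of the pattern, since 6 of 15 lay above the median detected signal on all 3 arrays. Among the genes well above background on all 3 arrays, 68.2% did. The shared ETEC array and its culture stay open too, as does an effect common to both lactobacilli.

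Cell cycle genes were higher on the TL2937+ETEC than on the TL2766+ETEC array. Their other probes, 10 probes of 7 genes, had a median log2 difference of 0.2329 (interval over probes 0.10 to 0.33), which argues against an artefact of single probes. The list median was 0.2953 after cyclic loess, which argues against brightness-dependent scaling as the whole cause. It was 0.2456 after the surrounding spots' median was subtracted, again a weak test of a local trend. A difference between the arrays therefore remained. A difference in growth between the cultures, from the lactobacilli or from chance, may underlie that difference and was not tested.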

How the results depend on the processing

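The alternatives for the correlation between the lactobacillus differences were chosen after seeing the data, and all others before. No paired analysis was possible because each group had 1 array, and a slide block was not possible because all arrays lay on 1 slide. Of values of list medians under the alternatives, 1068 moved by less than the spread of random lists, 177 moved by more, and 3 turned sign among the 41 medians outside the central 95%. Of the 64 medians inside it, 34 turned sign under at least 1 alternative, so their direction is not settled. Of values of named genes, 492 stayed within the median spot spread of the replicated probes, 83 moved and 1 changed sign. That spread is 1 value per comparison and was not measured for each gene. With normexp 65 of these values moved and 7 stayed. With the mean of all probes 18 moved, 53 stayed and 1 changed sign. Each other setting left all 72 unmoved. The authors' table is the same intensity rounded, and the outlier spots were few, so these settings could hardly move a gene. Median and spike-in scaling shift all genes of an array alike. No scaling moved the median of all genes by over 0.1, the largest shift being 0.036. Of 6523 genes with a symbol, 4922 were well above background on all 3 arrays. Of the 64 list medians inside the central 95%, 6 lay outside it under at least 1 scaling.

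Counts of genes 2-fold higher and lower are given for TL2937+ETEC against ETEC, TL2766+ETEC against ETEC and the direct comparison, in this order. They were 5 and 2, 5 and 2, and 1 and 0 with normexp, whose offset shrinks differences of dim genes. They were 57 and 57, 77 and 67, and 57 and 64 with either array above background, and 134 and 207, 153 and 273, and 205 and 169 with no filter, since these add dim genes. With both arrays above the median detected signal they were 4 and 2, 4 and 2, and 0 and 0. At 1.5-fold they were 53 and 111, 70 and 75, and 19 and 49, and at 3-fold 3 and 1, 5 and 1, and 0 and 2. With the mean of all probes, 12 were lower in the first comparison, and 9 were higher and 18 lower in the direct one.

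The following list medians moved, and the cause was not tested. Chemokines, TL2937+ETEC against ETEC: -0.1789 with normexp, -0.1754 above the median signal and -0.2346 over members measured on both arrays. In the direct comparison they were -0.2597 with quantile, -0.2327 with loess, -0.2513 with spike-in scaling, -0.3129 above the median signal and -0.3129 over members measured on both arrays. Complement was -0.1516 with normexp and -0.4191 above the median signal with TL2937, -0.05868 with normexp with TL2766, and -0.08845 with normexp, -0.2156 with loess and -0.2887 above the median signal in the direct comparison. Interferon-stimulated genes were -0.494 with normexp, -0.4604 with quantile, -0.4496 with loess and -0.4894 with the mean of probes with TL2937, -0.1842 with spike-in scaling with TL2766, and -0.2532 with quantile, -0.2515 with loess and -0.2624 with spike-in scaling in the direct comparison. Among the medians outside the central 95%, signs turned for cytokines with TL2766 and no filter (-0.004574), apoptosis genes with TL2766 and the mean of probes (0.0003524) and enterocyte markers with TL2766 over members measured on both arrays (0.0746), and among named genes for MATN2 in the direct comparison with the mean of probes (-0.06426, against 0.78). The correlation was 0.7823 with normexp, 0.6862 with the mean of probes, 0.6054 with either array above background, 0.5558 with no filter and 0.8105 above the median signal.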

Other observations

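Several other gene groups held single members that differed the same way on both lactobacillus arrays, although both were compared with the same ETEC array. Among adhesion molecules, ALCAM differed by -0.76 on the TL2937+ETEC array and -0.69 on the TL2766+ETEC array. The list medians were -0.051 (percentile 68.3) and -0.012 (percentile 48.8), and both turned sign under another scaling. Among lipid genes, the lipid droplet protein PLIN2 differed by 0.77 and 0.60 and the fatty acid transporter CD36 by -0.45 and -0.47, with list medians of -0.070 (percentile 19.9) and -0.0062 (percentile 42.6). Among junction and keratin genes, the tight junction gene CLDN1 differed by -0.48 and -0.48 and OCLN by -0.31 and -0.24, with list medians of -0.12 (percentile 9.65) and -0.043 (percentile 23.5). E-cadherin (CDH1) differed by 0.54 and CLDN3 by -0.54 on the TL2937+ETEC array.

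Markers of other cell types lay inside the central 95% of random lists in all 3 comparisons in the main setting. With normexp, the fibroblast and smooth muscle median on the TL2766+ETEC array was -0.1752 (percentile 0.2), and in the direct comparison endothelium reached percentile 97.8 with normexp and 99.28 with cyclic loess. Against ETEC, the medians on the TL2937+ETEC and TL2766+ETEC arrays were -0.14 and -0.14 for fibroblasts and smooth muscle, and -0.071 and 0.11 for macrophages and dendritic cells. They were -0.046 and 0.085 for endothelium, and 0.057 and 0.11 for goblet, Paneth and enteroendocrine cells, a list that holds SST. Lymphocyte markers, with 4 and 3 members measured on both arrays, are not described. The signs of all these but the fibroblast list turned under another scaling on at least 1 array. Among probes with no gene symbol, 50 were at least 2-fold higher and 47 lower of 15064 on the TL2937+ETEC array, and 61 higher and 52 lower of 14917 on the TL2766+ETEC array.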
